A study of Mus musculus with 18 samples.

How the data were processed

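Poly(A) RNA of bone marrow-derived macrophages was sequenced from stranded libraries (NEBNext Ultra II Directional, per the labels' protocols) in 18 samples, 6 in each of 3 groups. The deposited table holds whole-number counts of reads per gene, not normalized, as the values show. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.5.2 and 2.5.2b, featureCounts 1.5.1, RSEM 1.3.0 and FastQC 0.11.5 with the genome build GRCm38 (mm10). Which step each tool served, the annotation release, the filters and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes are uncertain. Counts of multigene families may be split among relatives.

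Gene IDs were matched to GENCODE M21, an annotation of the same build, which gave symbols for 48348 of 48794 rows; 446 had none. Samples were grouped by their titles. The libraries held 14793404 to 20056125 counts, and no library was a copy of another: the lowest chi-square per degree of freedom between 2 libraries of a group was 2.59 over 45 pairs. Intervals and floors (95%, 3 counts) cover counting error only.

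Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10), which left 13177, and counts were scaled by TMM. All 18 libraries were fitted in a quasi-likelihood model (robust), and 3 contrasts were tested at an adjusted p of 0.05: IL4_IL13 against Control, IL4_IL13_TNFa against IL4_IL13, and IL4_IL13_TNFa against Control. CPM values use the TMM-scaled library sizes. In all, 21 pathway and 9 cell type lists were tested with camera of limma 3.58.1 in R 4.3.3 (log2 CPM with a prior count of 2, preset correlation 0.01, at least 3 measured genes), which left 26 lists; the T and NK cell, mast cell and basophil, eosinophil and erythroid lists had 2, 2, 2 and 0 measured genes. With an estimated correlation only alternative activation was called, in both comparisons with Control. The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. That rule took the 8 largest rises and falls per comparison (5 against Control for the 3 cytokines) among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, up to 2 members per list, 12 genes named in advance, and 5 moved genes per direction. List members given as examples outside this rule (Cd80, Cd86, H2-DMb2 and Cd83) were chosen after their values were seen. Single-gene tests behind a list count are adjusted over all genes.

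Replicate numbers are shared by the groups. Deviations of same-numbered libraries from their group means correlated at 0.128 to 0.671 in all 18 pairs of libraries, and in 16 each library was the other's best match, so the numbers pair the libraries by the data; no label says why. The scripts were tested on simulated counts. For IL4_IL13 against Control (12820 genes run) 50.7%, 80.6% and 95.5% of genes changed 1.5-, 2- and 4-fold were recovered, with 8 unchanged genes called. For added TNFa (12838 genes) the shares were 49.3%, 88.1% and 95.5%, with 5 called, and for the 3 cytokines against Control (12830 genes) 62.7%, 83.6% and 95.5%, with 4 called. Each run changed only 66 or 67 genes per fold, raised and lowered alike, and held no link between same-numbered libraries. The real contrasts call far more genes, so these shares need not hold for them.

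Alternatives were size factors of DESeq2 1.42.0, library totals, no filter and a stricter filter (CPM of 5 in 6 libraries), DESeq2, limma voom, a replicate block, only the libraries compared, an estimated correlation and fry for the lists, and each library left out. A stromal marker covariate, leaving out the 3 libraries numbered 1, and the block with an estimated correlation were added after seeing the data, as were the exact tests of the paired stromal sums and of the mitochondrially coded share.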

Results

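Gene expression was measured by RNA sequencing in macrophages grown from the bone marrow of male C57BL/6 mice. Marrow cells were matured for 7 days with M-CSF, the growth factor of the macrophage lineage, and then kept for 24 h in 1 of 3 conditions. Control cells received M-CSF alone. The IL4_IL13 cells also received IL-4 and IL-13, the cytokines of type 2 immunity, at 10 ng/ml each. The IL4_IL13_TNFa cells received these 2 cytokines and TNFa, an inflammatory cytokine, each at 10 ng/ml. Each group held 6 libraries, numbered 1 to 6. The total count per library ranged from 15744544 to 19309743 in Control, from 14793404 to 20056125 in IL4_IL13 and from 15645117 to 17808553 in IL4_IL13_TNFa. The labels do not say that the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. All log2 fold changes below are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13177 genes. Where a single gene is given in full, the ± after its log2 fold change is an approximate standard error. It is the absolute log2 fold change over the square root of the test's F value. For genes with few counts in a group, leaving out 1 library can shift the log2 fold change by more than this. Coordinates are on GRCm38.

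The first principal component held 62.7% of the variance and ordered the groups from Control through IL4_IL13 to IL4_IL13_TNFa. The second held 19.9% and set the IL4_IL13 libraries apart from both other groups. On the third, with 6.90%, Control replicate 1 lay at 69.2 while the other controls lay between -18.2 and 2.35. In Control replicate 1, 1836 genes differed by over 2-fold from the mean of the other 5 controls, against at most 393 genes in any other library compared in the same way.

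**Figure D1:**
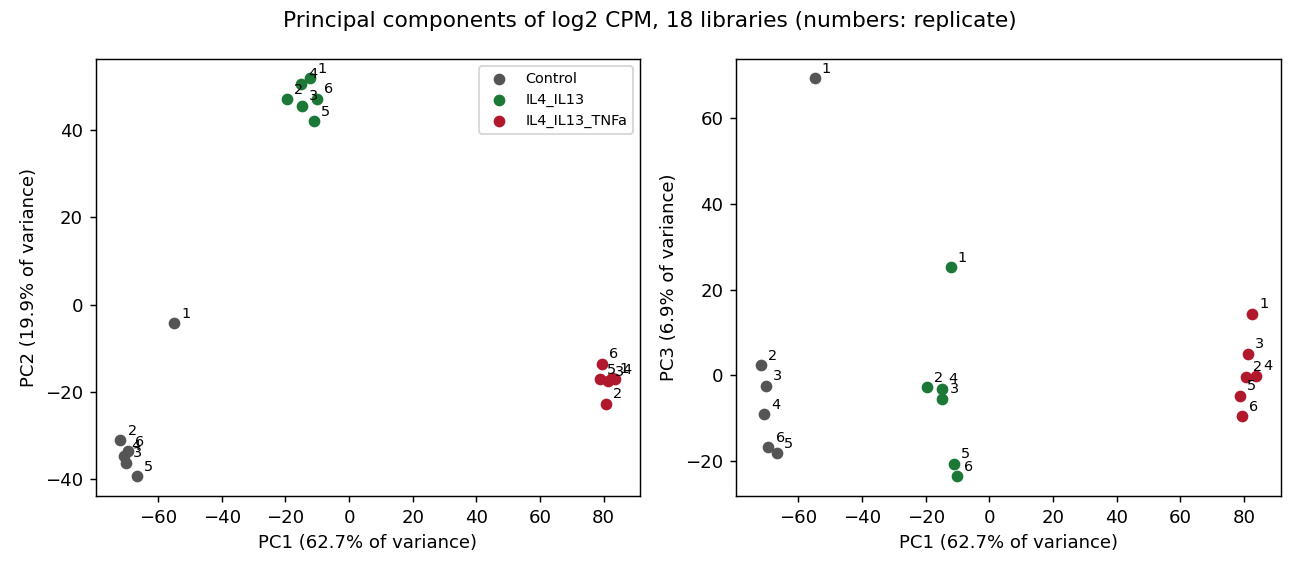
Principal components of log2 CPM for the 18 libraries, with component 1 (62.7% of the variance) on the x axis of both panels and component 2 (19.9%) or component 3 (6.90%) on the y axis. Each point is a library, coloured by group and marked with its replicate number; Control replicate 1 sits at 69.2 on component 3.

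The comparison of IL4_IL13 with Control asked what the 2 type 2 cytokines changed. Genes of alternative activation, the macrophage state linked to type 2 immunity, showed the largest median rise of the lists fixed in advance (19 of 19 higher), while 20 of 22 interferon response genes fell. The call of the first list held with an estimated correlation (adjusted p = 0.00195) and that of the second did not (adjusted p = 0.362). Retnla, which encodes the secreted protein Fizz1, rose from 0.0644 ± 0.132 to 1102 ± 466 CPM (SD, n = 6), a log2 fold change of 13.93 ± 0.58 (edgeR adjusted p = 6.2e-13; 15.89 without Control replicate 5). Arg1, which encodes the arginine-degrading enzyme arginase 1, rose from 0.470 ± 0.335 to 645.5 ± 219 CPM, a log2 fold change of 10.38 ± 0.36 (edgeR adjusted p = 7.19e-14). The mannose receptor gene Mrc1 rose 5.67-fold, from 222 ± 58.5 to 1260.0 ± 92.6 CPM. Cxcl10, an interferon-induced chemokine gene, fell from 10.2 ± 3.70 to 0.287 ± 0.254 CPM, a log2 fold change of -5.09 ± 0.41 (edgeR adjusted p = 6.2e-09).

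All 19 measured members of the alternative activation list rose, with a median log2 fold change of 5.50, and the list was called by camera (adjusted p = 8.87e-17, and 0.00195 with an estimated correlation). In the list, 19 of 19 members passed when adjusted over the list alone. Besides Retnla and Arg1, the list held Ear2, an eosinophil-associated ribonuclease gene on chromosome 14 from 44102654 to 44103534. It had 2 counts over all 6 controls and 7088 counts in IL4_IL13, a ratio of 3734 with a 95% counting interval of 1033 to 30840. The chemokine gene Ccl17 had 1 count in Control and 104 in IL4_IL13, a ratio of 109.6 with an interval of 19.2 to 4369. Ccl22, a chemokine gene, rose 13.4-fold. The list members Mgl2 and Chil3 rose by log2 fold changes of 10.26 ± 0.27 and 9.84 ± 0.29. Outside the list, Rnase2a on chromosome 14 from 51255262 to 51256112 rose by a log2 fold change of 12.54 ± 0.32. The homeobox gene Msx3 had 3 counts in Control and 2510 in IL4_IL13, a ratio of 881.6 with an interval of 301.3 to 4278. Tuba8, a tubulin gene, had 1 count in Control and 1100 in IL4_IL13, a ratio of 1159 with an interval of 207.6 to 45820. These ratios rest on few control counts: the fitted log2 fold change of Msx3 was 9.41, and 10.30 without Control replicate 2, that of Tuba8 9.31, and 10.45 without Control replicate 1, and that of Ccl17 5.93, and 7.08 without Control replicate 4. Ear2 and Rnase2a, and Chil3, belong to families of near-identical genes, so how reads were split among relatives is uncertain.

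Of 22 measured interferon response genes, 20 fell and none rose, with a median log2 fold change of -2.47. The list was called (adjusted p = 7.62e-09), but not with an estimated correlation (adjusted p = 0.362). Of these, 21 of 22 passed adjusted over the list alone. In Control replicate 1 the list lay below the other controls by a median log2 difference of -1.08. Ifit1 fell 20.7-fold and Ifit3 26.7-fold, the latter with a near-identical relative, Ifit3b, which fell 40.4-fold. Of 11 measured inflammatory mediators 7 fell, among them Tnf (log2 fold change -1.92 ± 0.23) and Il1b (-3.10 ± 0.48, and -3.91 without IL4_IL13 replicate 1), and the list was called (adjusted p = 0.0023, and 0.147 with an estimated correlation). Of 21 measured NF-kB target genes 14 fell and 4 rose, with Nfkbia, which encodes an inhibitor of NF-kB, lower by a log2 fold change of -0.82 ± 0.06 (adjusted p = 0.0228 for the list, and 0.504 with an estimated correlation). Of 17 cytokine and pattern receptor genes 10 fell and 4 rose, with Tlr2 5.22-fold and Cd14 4.05-fold lower (adjusted p = 0.00873, and 0.423 with an estimated correlation). Of 13 macrophage identity genes 8 fell and 2 rose, and the chemokine receptor gene Cx3cr1 fell from 888 ± 46.9 to 67.6 ± 13.3 CPM (adjusted p = 0.00181 for the list, and 0.147 with an estimated correlation). Adjusted over the list alone, 7 inflammatory mediators, 18 NF-kB targets, 15 receptors and 11 identity genes passed. Il4ra, which encodes a subunit of the IL-4 receptor, fell from 128 ± 12.5 to 57.3 ± 5.32 CPM, while Tnfrsf1b, a TNF receptor gene, rose 1.57-fold. Nos2 was at 0.0789 ± 0.0900 CPM in IL4_IL13 and 0.263 ± 0.327 CPM in Control and did not pass the test (edgeR adjusted p = 0.162). Ly6a, Gpr162, Ms4a6b and Ndrg2 were among the largest falls, at 22.9-, 19.5-, 15.2- and 25.4-fold.

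All 22 oxidative phosphorylation and TCA cycle genes were higher with IL4_IL13, with a median log2 fold change of 0.70 (adjusted p = 2.56e-11, and 0.226 with an estimated correlation), among them Idh3a (2.54-fold) and Atp5b (2.10-fold). The share of counts from mitochondrially coded genes was 1.27% ± 0.0750 in Control (SD, n = 6) and 0.230 percentage points higher in IL4_IL13, with an SD of 0.119 (exact permutation p = 0.00866, two-sided, adjusted over 3 comparisons 0.013). Paired by replicate number the share was higher in 5 of 6 numbers and did not pass (exact sign-flip permutation p = 0.0625, and 0.0625 adjusted). Of 18 fatty acid genes 12 rose and 2 fell, led by Ppargc1b and Fabp4 at 9.36- and 8.69-fold (adjusted p = 0.000169, and 0.102 with an estimated correlation). Cholesterol synthesis (11 of 20 up, adjusted p = 0.0023, and 0.504 with an estimated correlation), glycolysis (11 of 18 up and 3 down, adjusted p = 0.0126, and 0.504 with an estimated correlation) and arginine and polyamine metabolism (7 of 13 up and 1 down, adjusted p = 0.00437, and 0.39 with an estimated correlation) were also called. So were ER stress and amino acid response (12 of 15 up and 1 down, adjusted p = 0.00172, and 0.102 with an estimated correlation) and osteoclast and cell fusion (9 of 12 up and 3 down, adjusted p = 0.00181, and 0.0642 with an estimated correlation). In the last list Ocstamp, a gene needed for fusion of osteoclast precursors, rose from 0.322 ± 0.380 to 87.9 ± 18.2 CPM, by a log2 fold change of 8.75 without Control replicate 1 against 7.98 with it. Adjusted over the list alone, 22 oxidative, 14 fatty acid, 11 cholesterol synthesis, 15 glycolysis, 9 polyamine, 14 ER stress and 12 osteoclast genes passed. Control replicate 1 differed from the other controls in several of these lists, with median log2 differences of 1.39 for polyamine, 0.92 for glycolysis, 0.72 for cholesterol synthesis, 0.50 for ER stress and 0.40 for oxidative genes.

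Of 20 cell cycle genes 12 rose and none fell (median log2 fold change 0.62, adjusted p = 0.0023, and 0.504 with an estimated correlation; 12 passed adjusted over the list alone). The summed CPM of the list was 4461 in Control replicate 1 against 1085 to 1958 in the other controls. Without that library the median was 0.93. MHC class II presentation genes went both ways, with 10 of 13 up and 3 down: Cd74 rose 4.98-fold, while Cd86 and Cd80, which encode costimulatory ligands, and H2-Oa fell. That list was not called (adjusted p = 0.0588) but was with the replicate number as a block (adjusted p = 0.028), with the stricter filter (adjusted p = 0.0185), and when IL4_IL13 replicate 1, or Control replicate 3, 4, 5 or 6, was left out (adjusted p of 0.0397, 0.0425, 0.0497, 0.0356 and 0.0369). Phagocytosis and lysosome genes, with 10 of 18 down and 3 up, were not called (adjusted p = 0.0597), but were with the block (adjusted p = 0.035), with the stricter filter (adjusted p = 0.0461), without Control replicate 1 (adjusted p = 0.0331) and without the libraries numbered 1 (adjusted p = 0.0428). With an estimated correlation neither list was called (adjusted p = 0.504 for both), nor was either with the block and an estimated correlation. MHC class I (3 of 13 up, 4 down), matrix and growth factors (9 of 22 up, 3 down), cholesterol efflux (4 of 11 up, 3 down), NRF2 (3 of 12 up, 3 down) and hypoxia genes (2 of 11 up, 5 down) were not called, with adjusted p of 0.718, 0.199, 0.525, 0.945 and 0.324. Adjusted over the list alone, 13 MHC class II, 14 phagocytosis, 7 MHC class I, 12 matrix, 8 efflux, 6 NRF2 and 7 hypoxia genes passed. Control replicate 1 lay apart from the other controls by a median log2 difference of -1.06 for MHC class II and 1.05 for NRF2 genes. The matrix list had a negative median (-0.02) and a positive mean (0.39), and the NRF2 list a negative median (-0.03) and a positive mean (0.09) with camera pointing down. Within the matrix list, the elastase gene Mmp12 rose from 50.9 ± 18.2 to 2123 ± 202 CPM.

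In total 7774 of 13177 genes changed, 3865 higher and 3909 lower, of which 1631 changed at least 2-fold. Scaling by library totals alone left 44.2% of called genes higher, against 49.7%. Without Control replicate 1, 9081 genes were called.

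**Figure D2:**
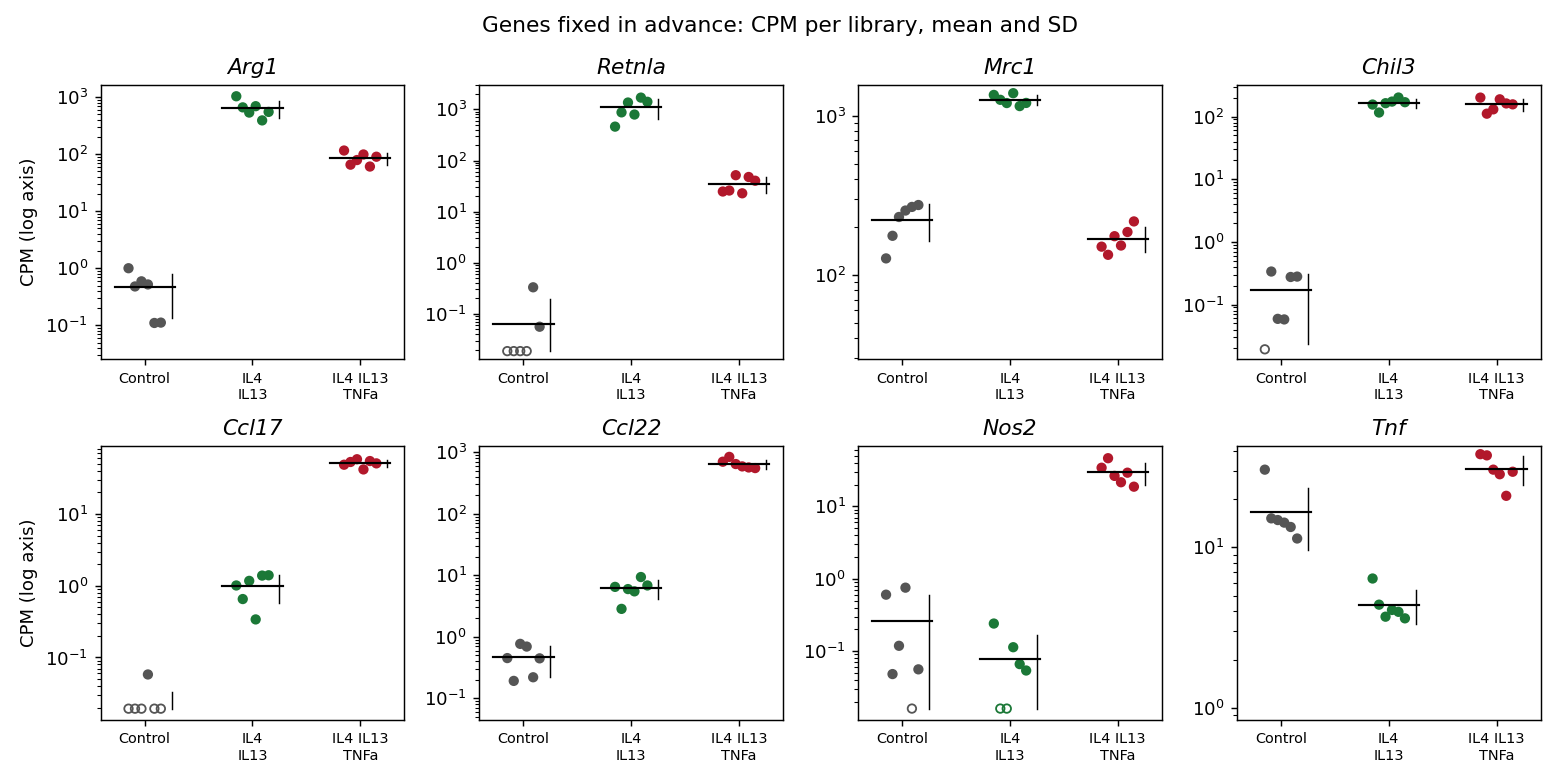
CPM of 8 genes fixed in advance (log y axes) in the 3 groups on the x axis, with a point per library, a line at the mean and a bar of 1 SD at its right end; open circles on the lower edge are libraries with 0 counts and a bar that would pass the lower edge stops there. Retnla, Arg1 and Mrc1 are highest in IL4_IL13, while Ccl17, Ccl22 and Nos2 are highest in IL4_IL13_TNFa.

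The comparison of IL4_IL13_TNFa with IL4_IL13 asked what TNFa changed in cells that also received the 2 type 2 cytokines. With no group given TNFa alone, no interaction could be fitted. Of the measured genes, 19 of 21 NF-kB targets, 13 of 13 MHC class I and 9 of 13 MHC class II genes rose, 20 of 20 cell cycle genes fell, and the alternative activation list split. The calls of the first 4 lists were lost with an estimated correlation (adjusted p = 0.179, 0.301, 0.626 and 0.496). Acod1, which encodes the itaconate-producing enzyme, rose from 2.55 ± 4.22 to 968.5 ± 140.3 CPM (SD, n = 6), a log2 fold change of 8.47 ± 0.67 (edgeR adjusted p = 3.22e-09). Its level was 11.1 CPM in IL4_IL13 replicate 1, and without that library the log2 fold change was 10.19. Nos2, the inducible nitric oxide synthase gene, rose from 0.0789 ± 0.0900 to 29.5 ± 9.97 CPM (8.31 ± 0.51 on the log2 scale, edgeR adjusted p = 9.9e-11, and 9.07 without IL4_IL13 replicate 1). Retnla fell from 1102 ± 466 to 35.5 ± 12.6 CPM, a log2 fold change of -4.95 ± 0.33 (edgeR adjusted p = 2.6e-10).

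The alternative activation list had 9 members higher, 8 lower and 2 not past the threshold, with a median log2 fold change of -0.04, and was not called (adjusted p = 0.684). Arg1 fell 7.58-fold and Mrc1 7.43-fold, and Ear2 fell 24.3-fold. Ccl22 rose from 6.17 ± 2.12 to 649 ± 109 CPM and Ccl17 from 0.994 ± 0.424 to 51.3 ± 5.62 CPM, log2 fold changes of 6.72 ± 0.22 and 5.69 ± 0.20. Chil3 was at 158 ± 33.9 and 163 ± 27.9 CPM and did not pass the test (edgeR adjusted p = 0.827). Of the list, 17 of 19 passed adjusted over the list alone.

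Of 21 NF-kB target genes 19 rose, 1 fell (Cd83) and 1 did not pass, with a median log2 fold change of 2.49 (adjusted p = 1.48e-11, and 0.179 with an estimated correlation; 20 passed adjusted over the list alone). Tnfaip3, a feedback inhibitor of NF-kB, rose 12.9-fold, Nfkbia 5.60-fold and the adhesion gene Vcam1 34.4-fold. Of 11 inflammatory mediators 6 rose and 2 fell, among them Cxcl3 at 110.6-fold (log2 fold change 6.79, and 10.39 without IL4_IL13 replicate 1) and Tnf at 7.03-fold; the list was called (adjusted p = 0.0405, and 0.481 with an estimated correlation), but not without Control replicate 1 (adjusted p = 0.0583) or IL4_IL13 replicate 2 (adjusted p = 0.0571). Interferon response genes rose from their lowered level in IL4_IL13, with 20 of 22 higher and none lower (adjusted p = 3.62e-06, and 0.561 with an estimated correlation), led by Gbp2 at 63.0-fold. All 13 MHC class I genes rose, among them the peptide loading gene Tapbp at 2.69-fold (adjusted p = 1.15e-06, and 0.301 with an estimated correlation). Of 13 MHC class II genes 9 rose and 1, H2-DMb2, fell (adjusted p = 0.0107, and 0.626 with an estimated correlation), and H2-Eb1 rose from 151 ± 57.4 to 1037 ± 124 CPM. NRF2 and oxidative stress genes rose, with 10 of 12 higher (adjusted p = 1.42e-06, and 0.301 with an estimated correlation). Slc7a11, a cystine transporter gene, was 69.8-fold higher and Nqo1 10.1-fold. Adjusted over the list alone, 8 inflammatory mediators, 20 interferon, 13 MHC class I, 11 MHC class II and 10 NRF2 genes passed. Reads of MHC genes may be split among near-identical relatives.

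All 20 cell cycle genes fell, with a median log2 fold change of -2.69 (adjusted p = 3.87e-08, and 0.496 with an estimated correlation; 20 passed adjusted over the list alone). The mitotic genes Ccnb2 and Plk1 fell 17.4- and 16.5-fold. The summed CPM of the list was 562 to 781 in IL4_IL13_TNFa and 2406 to 4396 in IL4_IL13, while the summed stromal markers were lower with added TNFa in 6 of 6 replicate numbers. Of 18 phagocytosis and lysosome genes 12 fell and 4 rose (adjusted p = 0.00473, and 0.481 with an estimated correlation; 17 passed adjusted over the list alone), with the scavenger receptor gene Cd163 11.7-fold and Cd5l 10.4-fold lower. All 22 oxidative phosphorylation and TCA cycle genes rose again (median log2 fold change 0.60, adjusted p = 1.39e-08, and 0.481 with an estimated correlation), while the mitochondrially coded share ranged from 1.47% to 1.76% in IL4_IL13_TNFa, 0.147 percentage points higher in the mean (n = 6, exact permutation p = 0.039, two-sided, the same after adjustment) and higher in 6 of 6 replicate numbers (exact sign-flip permutation p = 0.0312, adjusted 0.0469). Also higher were 9 of 18 glycolysis genes (adjusted p = 0.014, and 0.771 with an estimated correlation) and 9 of 20 cholesterol synthesis genes, with 2 lower (adjusted p = 0.0405, and 0.771 with an estimated correlation). The last call was lost without IL4_IL13 replicate 5 (adjusted p = 0.0506) or IL4_IL13_TNFa replicate 5 (adjusted p = 0.0509). In these 3 lists 22, 9 and 11 genes passed adjusted over the list alone. Matrix and growth factors (6 of 22 up, 9 down), fatty acid (6 of 18 up, 7 down), cholesterol efflux (3 of 11 up, 3 down), polyamine (5 of 13 up, 2 down), osteoclast (5 of 12 up, 6 down), receptor (8 of 17 up, 7 down), ER stress (5 of 15 up, 3 down), hypoxia (2 of 11 up, 6 down) and macrophage identity genes (5 of 13 up, 6 down) went both ways and were not called, with adjusted p of 0.684, 0.684, 0.665, 0.349, 0.752, 0.488, 0.515, 0.349 and 0.515. Adjusted over the list alone, 16, 13, 6, 7, 11, 15, 8, 9 and 11 of their genes passed. Median and mean differed in sign for the alternative activation (-0.04 and 0.21), matrix (-0.54 and 0.10), fatty acid (0.02 and -0.20), ER stress (0.08 and -0.05) and macrophage identity lists (0.15 and -0.59), and camera pointed down for the osteoclast list, whose median was 0.01. The positive medians of the fatty acid, efflux, polyamine, osteoclast, receptor, ER stress and identity lists turned negative with library totals. Within the matrix list, the gelatinase gene Mmp9 rose from 2.69 ± 2.63 to 807 ± 164 CPM and the membrane protease gene Mmp14 rose 28.2-fold.

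Macc1 had 0 counts in the 6 IL4_IL13 libraries and 869 in IL4_IL13_TNFa, at least 338.5-fold higher against a floor of 3 counts over the group. H2-M2, Artn, Lad1 and Rtn4rl2 rose by log2 fold changes of 8.98 ± 0.68, 8.90 ± 0.44, 7.65 ± 0.34 and 7.35 ± 0.26. Without IL4_IL13 replicate 1 the first 3 were 10.69, 10.40 and 8.89. Hpgd, which encodes a prostaglandin-degrading enzyme, fell 168-fold from 113 ± 20.8 CPM, and Cd300lg, Slco2b1, Scn3a, Msx3, Cd300lf, Ang and Depdc1b fell 79.8-, 72.4-, 68.9-, 68.4-, 50.3-, 43.8- and 41.7-fold. Il4ra rose 1.67-fold and Tnfrsf1b 1.39-fold, the latter not past the threshold with library totals (adjusted p = 0.153).

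In total 7856 genes changed, 3999 higher and 3857 lower, of which 2308 changed at least 2-fold. The split depends on scaling: with library totals and no composition factor 2313 genes were higher and 6089 lower, 27.5% higher instead of 50.9%, and the median of all genes shifted to -0.20 on the log2 scale. The 50 most abundant genes held 19.1% to 19.6% of the counts in the IL4_IL13_TNFa libraries and 13.3% to 14.8% in the IL4_IL13 libraries. Under that scaling 20 of 22 oxidative genes, 17 of 22 interferon genes and all 13 MHC class I genes were still higher, and all 20 cell cycle genes lower, while glycolysis had 9 higher and 3 lower and cholesterol synthesis 7 higher and 4 lower.

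**Figure D3:**
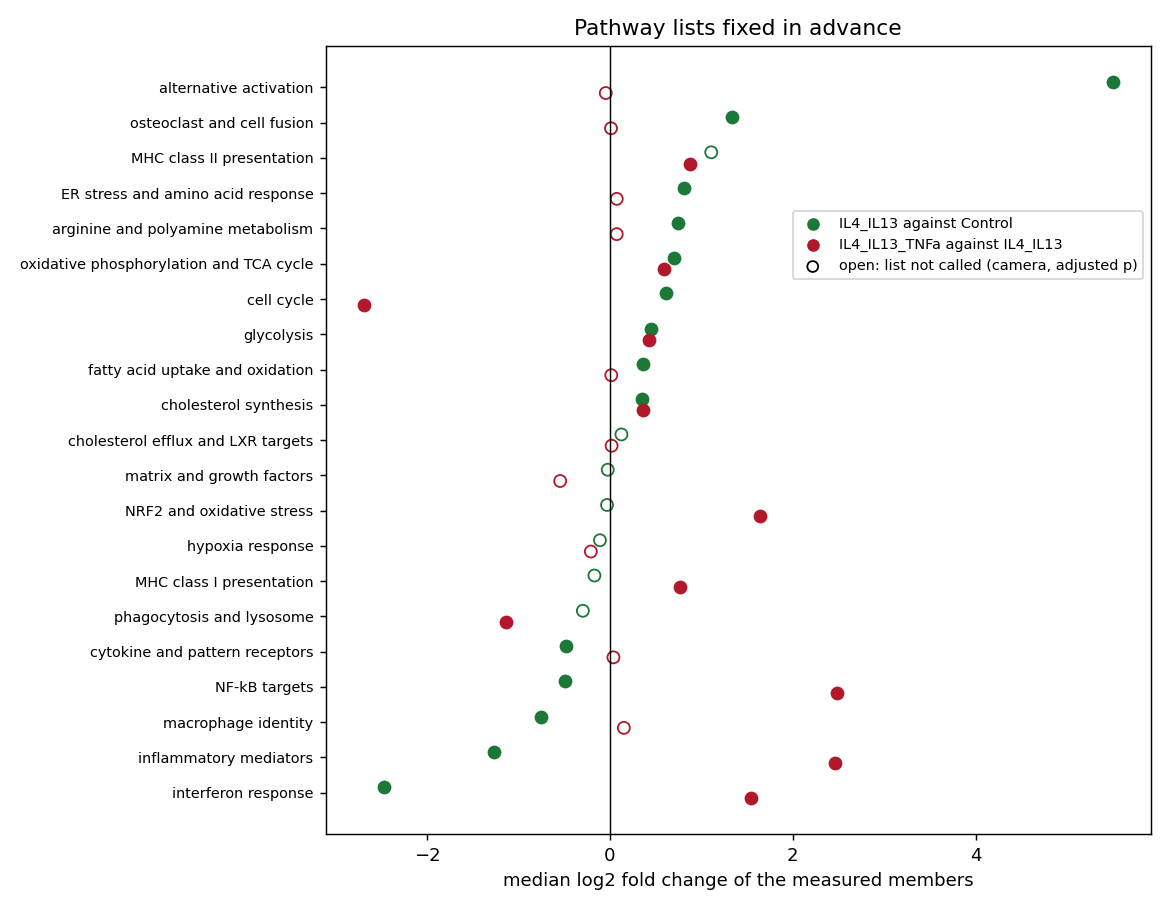
Median log2 fold change (x axis) of the measured members of the 21 pathway lists (y axis) for IL4_IL13 against Control (green) and IL4_IL13_TNFa against IL4_IL13 (red), with open circles for lists that camera did not call. Alternative activation lies at 5.50 and -0.04, and cell cycle at 0.62 and -2.69.

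The comparison of IL4_IL13_TNFa with Control asked what the 3 cytokines did together. Alternative activation genes were 16 up, 1 down and 2 not past the threshold (median log2 fold change 6.79, adjusted p = 1.5e-08, and 0.0482 with an estimated correlation). Of 22 interferon response genes 5 were higher and 12 lower than in Control (median log2 fold change -0.56, camera adjusted p = 0.235, not called). Inflammatory mediators split, with 5 of 11 up and 5 down (camera adjusted p = 0.897, not called). Rnase2a, Ccl22, Chil3 and Apol7c rose by log2 fold changes of 12.06 ± 0.32, 10.46 ± 0.28, 9.79 ± 0.29 and 9.69 ± 0.44, the last 11.22 without Control replicate 5. Ccl17 had 1 count in Control and 4625 with the 3 cytokines, a ratio of 5695 with an interval of 1022 to 224989. Retnla was 504-fold and Arg1 176-fold higher than in Control, Nos2 109.5-fold and Tnf 1.86-fold. On the log2 scale Retnla was at 10.93 without Control replicate 5 against 8.98, and Nos2 at 7.37 without Control replicate 4 against 6.77. Tnfaip3 and Nfkbia rose 7.28- and 3.17-fold, Tnfrsf1b rose 2.18-fold and Il4ra fell 1.34-fold. Mrc1 fell 1.31-fold (edgeR adjusted p = 0.0304), a call lost when any of Control replicates 3 to 6 or IL4_IL13_TNFa replicates 1, 2 or 4 was left out, with adjusted p between 0.0507 and 0.0798, and also with no filter (adjusted p = 0.172) and with only the libraries compared (adjusted p = 0.0617). Hpgd, Ighm, Tpbgl and Slco2b1 fell 859-, 417-, 259- and 231-fold. On the log2 scale Ighm was at -9.29 without IL4_IL13_TNFa replicate 6 against -8.70, and Tpbgl at -8.63 and -8.64 without IL4_IL13_TNFa replicate 1 or 2 against -8.02. Gpr34 fell from 1891 counts to 1, a ratio of 1536 with an interval of 275 to 60689. The fitted log2 fold change of Gpr34 was -9.89, and -11.22 without IL4_IL13_TNFa replicate 1, and that of Ccl17 was 11.62, and 12.77 without Control replicate 4. In total 9722 genes changed, 4803 higher and 4919 lower, 3500 at least 2-fold. With library totals 32.7% of the called genes were higher, against 49.4%, with a median shift of -0.27 on the log2 scale. Of 26 lists tested, 15 were called, 12 up and 3 down, against 14 for IL4_IL13 and 11 for added TNFa. With an estimated correlation 1, 1 and 0 were called.

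Genes changed by IL4_IL13 could move back or further with added TNFa. Of 3865 raised genes, 1038 (26.9%) were lowered and 1632 (42.2%) raised further. Of 3909 lowered genes, 961 (24.6%) were raised and 1467 (37.5%) lowered further. Both comparisons use the IL4_IL13 libraries, with opposite signs. Independent lists would give 1131 raised then lowered, 1186 lowered then raised, 1173 raised further and 1144 lowered further. Simulated unchanged groups gave 0 of each. With no changed genes in them hardly any overlap was possible, so they say nothing about overlap among changed genes. With the IL4_IL13 libraries split into 2 sets of 3, the medians over 20 splits and orders were 715.5, 696.5, 1271 and 1187. Each comparison then used 3 IL4_IL13 libraries instead of 6, and the lower power can lower these counts. Across genes, which are not independent replicates, the fold changes correlated at 0.0199, against -0.497 in the simulations, and had a covariance of 0.0189 against -0.0171. The simulated values hold no real changes and reflect the shared libraries. In the splits, which share no library, the median correlation was 0.0310 (-0.0140 to 0.0625), a range that holds the observed value. Raised then lowered were Retnla, Ear2, Msx3, Scn3a and Ablim1, and lowered then raised were P2ry13, Gpr84, Clec4n, Clec4e and Gbp5; Clec4n fell 6.74-fold and then rose 119-fold. Without IL4_IL13 replicate 1 the log2 fold changes of Clec4e were -3.13 and 6.03, against -2.54 and 5.44. Raised further were Ccl17, Ccl22, Itgb8, Tnfaip8l3 and Car2, of which Itgb8, an integrin gene, rose from 0.337 ± 0.176 to 5.49 ± 0.835 and then to 101.3 ± 12.2 CPM (SD, n = 6). Lowered further were Ighm, Gpr34, Ctla2a, Ctla2b and Ndrg2. Ctla2a and Ctla2b are near-identical relatives, and the fall of Ighm with added TNFa was not called by limma voom (adjusted p = 0.0935).

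Markers of other cell types were present at different levels. The summed CPM of the 10 stromal markers was 317 ± 246 in Control, 269 ± 199 in IL4_IL13 and 176 ± 122 in IL4_IL13_TNFa (SD, n = 6), with a range of 30.7-fold within Control, and 0 of 8 measured stromal genes passed the test in any comparison, when the libraries were not paired, except that 1 was lower with the 3 cytokines against Control under library totals and 1 without the libraries numbered 1. With the replicate number as a block 4 of 8 were lower with added TNFa and 4 of 8 with the 3 cytokines against Control. Paired by number, the ratio of the stromal sum in IL4_IL13_TNFa to that in IL4_IL13 was 0.559 to 0.974, lower in 6 of 6 numbers (exact sign-flip permutation p = 0.0312, two-sided, the smallest that 6 pairs can give, and 0.0938 adjusted over 3 comparisons). With the stromal covariate 1 of 8 was lower with added TNFa, and 1 was higher and 1 lower with the 3 cytokines. That covariate is the mean log2 CPM of these same 8 genes. It removes their common fall by construction, so these counts cannot test that fall. Control replicate 1 lay below the other controls by a median log2 difference of -3.63 for stromal and -1.04 for B cell markers. Of the B cell markers, Ighm fell from 72.5 ± 38.4 CPM in Control to 5.92 ± 2.65 and 0.164 ± 0.163 CPM, and Cd79b fell with IL4_IL13 from 1.57 ± 0.582 to 0.725 ± 0.156 CPM, while Ebf1 did not pass the test in any comparison. The T and NK cell sum was 92.9 ± 7.02 CPM in Control (SD, n = 6) and ranged from 152 to 185 CPM in IL4_IL13 and from 239.8 to 316 CPM in IL4_IL13_TNFa. Of it Il7r, the gene of an interleukin-7 receptor subunit, gave 91.0 ± 6.93, 164 ± 11.8 and 264 ± 28.2 CPM (SD, n = 6), and rose with IL4_IL13 (log2 fold change 0.84 ± 0.07) and again with added TNFa (0.69 ± 0.07). The other measured gene, Cd4, fell with IL4_IL13 from 1.13 ± 0.336 to 0.147 ± 0.182 CPM (log2 fold change -2.84, and -3.68 without IL4_IL13 replicate 6). The endothelial sum was 103 ± 9.07, 108 ± 11.2 and 115 ± 2.41 CPM, mostly from Eng. Pecam1 rose 11.9-fold with IL4_IL13, while Kdr fell 6.43-fold, and Cdh5 and Eng did not pass. Of the dendritic cell markers, Batf3 and Zbtb46 rose 51.5- and 3.86-fold with IL4_IL13 and Flt3 fell, from 0.858 ± 0.321 to 0.541 ± 0.0965 CPM. With added TNFa Zbtb46 rose to 33.9 ± 1.28 CPM from 2.76 ± 0.919, and Batf3 fell to 31.2 ± 4.36 from 50.8 ± 14.3. Of 3 measured neutrophil markers only Cxcr2 passed with IL4_IL13, with log2 fold changes of 0.15 ± 0.11 for Mmp8, the most abundant at 27.8 ± 4.96 CPM in Control, and -0.52 ± 0.34 for Mpo. Cxcr2 rose 106-fold from 4 counts with IL4_IL13 (log2 fold change 6.73, and 7.33 without Control replicate 4), and from there by a log2 fold change of 1.60 with added TNFa. The eosinophil marker Siglecf rose 16.5-fold and then from 20.6 ± 1.61 to 50.7 ± 2.70 CPM, while Ccr3 was at 8.10 ± 2.42 CPM in Control and 11.6 ± 2.71 CPM in IL4_IL13, a rise (adjusted p = 0.0347) that did not pass with library totals (adjusted p = 0.0504), with only the libraries compared (adjusted p = 0.0518) or without the libraries numbered 1 (adjusted p = 0.0807). It was also lost without Control replicate 1 or 2 or IL4_IL13 replicate 3, 4 or 6 (adjusted p = 0.0602, 0.0814, 0.054, 0.0946 and 0.0598). Of the 5 cell type lists with at least 3 measured genes, camera called none in any comparison. By fry, which does not compare a list with other genes, the neutrophil, dendritic cell and B cell lists were called for IL4_IL13 (adjusted p = 3.24e-11, 3.92e-10 and 0.00229). For added TNFa fry called these 3 (adjusted p = 7.42e-08, 0.000648 and 0.0111) and the endothelial list (adjusted p = 0.000612), and against Control for the 3 cytokines the same 4 (adjusted p = 8.54e-14, 8.3e-12, 8.34e-06 and 0.0212).

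**Figure D4:**
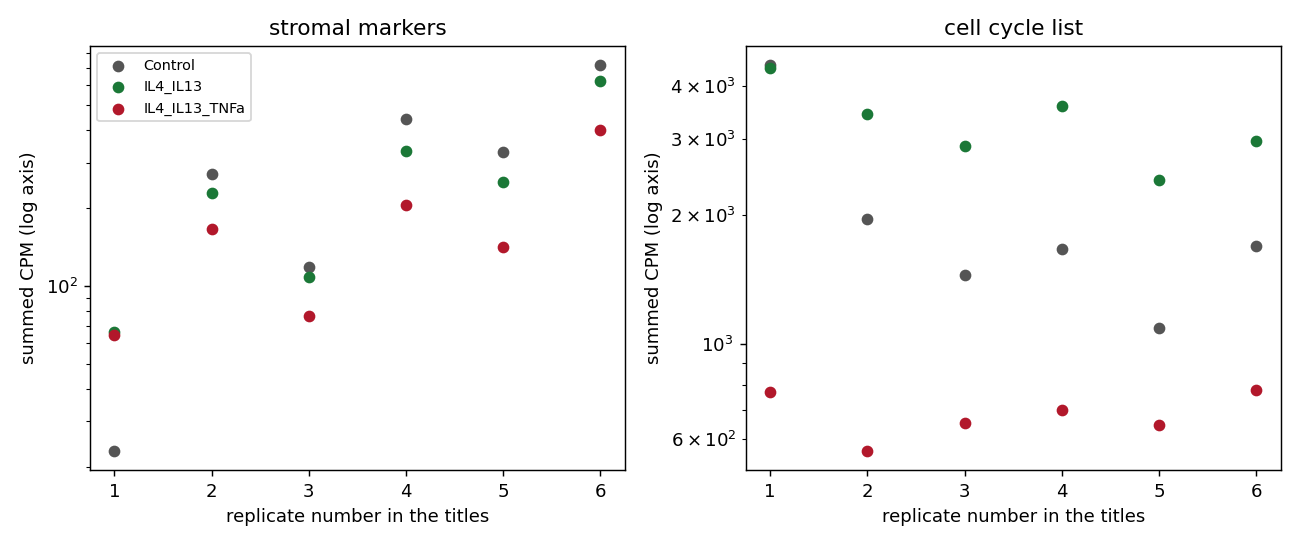
Summed CPM (log y axes) of the measured stromal markers and of the cell cycle list against the replicate number on the x axis, 1 point per library, coloured by group. Control replicate 1 has the lowest stromal sum, 23.0, and the highest cell cycle sum, 4461.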

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

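Tests of the stromal markers and of Control replicate 1 were chosen after the result was seen, as were those of the cell cycle genes; the counts over other splits of the samples were planned. Each group of 6 libraries was searched for a library far from the rest, where the gap to the nearest other library, as a share of the group's whole range, passed Dixon's 95% value. For independent, normally distributed values chance alone passes it in about 1 in 20 groups. CPM values were not transformed, and genes of a library can move together, so that rate need not hold here. Of 446 sets of 6 values, 73 did: 72 of 398 sets for the named genes, 0 of 21 for library measures and 1 of 27 for cell type markers. Control replicate 1 was the library in 41 of the 72 gene sets and IL4_IL13 replicate 1 in 14.

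In Control replicate 1 the highest values, with their gap ratios, were Acod1 0.834, Acsl1 0.849, Asns 0.928, Ass1 0.814, Atp5b 0.852, Ccl2 0.960, Ccne1 0.868, Chac1 0.839, Clec4e 0.876, Cox5a 0.780, Ctla2a 0.768, Dcstamp 0.885, Dhcr7 0.651, Gpr84 0.903, H2-M2 0.928, Idh3a 0.912, Il1rn 0.774, Kdr 0.687, Lss 0.646, Mdh2 0.854, Mmp9 0.670, Nqo1 0.677, Nsdhl 0.657, Pcna 0.869, Pfkl 0.799, Pfkp 0.874, Plk1 0.701, Slc16a1 0.912, Slc2a1 0.874, Slc7a11 0.848, Tnf 0.801, Tuba8 1. The lowest were Atf3 0.684, Cd14 0.707, Fcgr1 0.625, Gbp5 0.646, Hpgd 0.805, Maf 0.735, Mertk 0.794, Ms4a6b 0.643, Psmb10 0.757. The Tuba8 ratio rests on 1 count.

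In IL4_IL13 replicate 1 the gap ratios were Acod1 0.874, Acsl1 0.637, Artn 0.720, Ccl2 0.771, Clec4e 0.754, Cxcl2 0.834, Cxcl3 0.966, Gpr84 0.693, H2-M2 0.878, Il1b 0.687, Kdr 0.790, Lad1 0.722, Tnf 0.719 for high values and Hpgd 0.666 for low ones. Elsewhere the ratios were Ccl17 1 in Control replicate 4 (1 count); Apol7c 0.746, Retnla 0.831, Scn3a 0.628 in Control replicate 5; Gata2 0.629, H2-Oa 0.781 in Control replicate 6; Ang 0.627 in IL4_IL13 replicate 2; Ctla2a 0.776 in IL4_IL13 replicate 4. They were also Gbp2 0.632, Zbtb46 0.641 in IL4_IL13 replicate 5; Cdh5 0.798, Psme2 0.752 in IL4_IL13 replicate 6; Gpr34 1 (1 count), Il1b 0.886 in IL4_IL13_TNFa replicate 1; Apol7c 0.706 in IL4_IL13_TNFa replicate 2; Cdh5 0.798, Fcgr1 0.680 in IL4_IL13_TNFa replicate 3. The summed mast cell and basophil markers gave 0.645 in Control replicate 5.

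The summed stromal markers followed the replicate number across groups. On the log2 scale over 6 numbers, Pearson's r and Spearman's rho were 0.958 and 1 between Control and IL4_IL13 (exact permutation p = 0.00139 and 0.00278, adjusted over 3 relations 0.00417 and 0.00833), and r was 0.988 without the 2 numbers farthest from the median. Between IL4_IL13 and IL4_IL13_TNFa they were 0.982 and 0.943 (exact permutation p = 0.00278 and 0.0167, adjusted 0.00417 and 0.0167, r = 0.972 without 2), and between Control and IL4_IL13_TNFa 0.897 and 0.943 (exact permutation p = 0.0111 and 0.0167, adjusted 0.0111 and 0.0167, r = 0.934 without 2). The largest range within a group was 31.1-fold and the largest ratio of group means 1.81. The 8 measured markers rose and fell together within groups, with a median pairwise correlation of 0.934, so a share of stromal cells that differs between replicate numbers may account for it; why the numbers differ stays open, and no biological explanation was tested.

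Control replicate 1 had 1836 genes over 2-fold from the other controls. Its 0 counts of Retnla allow at most 0.0137% of an IL4_IL13 library, and its 0 counts of Ccl17 at most 0.293% of an IL4_IL13_TNFa library, which argues against carry-over from either. Loss of stromal RNA does not raise the rest by enough, since genes at least 4-fold lower there held 1.15% of the counts of the other controls. The other libraries numbered 1 shared part of the deviation. Its correlation with that of IL4_IL13 replicate 1 was 0.671, and with that of IL4_IL13_TNFa replicate 1 it was 0.312. On component 3 these libraries lay at 25.3 and 14.4, the highest of their groups. A fault of Control replicate 1 alone would leave that shared part unexplained. Other sources, such as a different culture or a different sample, stay open, and no biological explanation was tested.

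All 20 cell cycle genes fell with added TNFa. With the stromal markers as a covariate the median log2 fold change was -2.80, and with library totals -2.90, which argues against a lower stromal share or the scaling as the whole cause. The summed CPM of the list was lower in each of the 6 replicate numbers, by 3.72-fold at least and 6.10-fold at most, so it does not rest on 1 number. An untested hypothesis is that added TNFa may lower the share of cycling cells or their expression per cell, which bulk RNA does not separate. Other causes were not tested.

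Other splits of the 12 libraries of each comparison were fitted to see whether they call as many genes. They were all 32 splits that part every same-numbered pair, the real one included, and 68 drawn with a fixed seed from the other 430. In each comparison 1 of the 100 splits, the real one, gave as many genes. The real count was 7774 for IL4_IL13 against Control, with 7303 the highest other; 7856 for added TNFa, with 3891; and 9722 for the 3 cytokines against Control, with 7448. Among the splits that part all pairs, the highest others were 5661, 3687 and 7262. The highest others of all splits kept 5 of the 6 libraries of each group in place, and the median of the others was 0. Splits that mix the groups put the treatment difference into the spread within groups, so low counts there are largely built in. The labels do not set separate cultures apart, so the splits cannot exclude chance differences between cultures.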

How the results depend on the processing

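Tests with 3 alternatives were chosen only after the result was seen: the stromal covariate, leaving out the libraries numbered 1, and the replicate block with an estimated correlation; the others were planned. No called named gene changed sign, nor did a called list where it was retested. Lists were not retested with library totals, no filter, DESeq2, limma voom, only the libraries compared or the stromal covariate. With library totals, medians of uncalled lists and the balance of higher and lower genes changed sign. For added TNFa the Rps family went from 14 higher and 1 lower to 3 higher and 14 lower. Of 5377 values of named genes under the alternatives, 5330 stayed on their side of the threshold and 47 lost it; of 1938 values of gene lists 1820 stayed, 80 lost and 38 gained a call. With the replicate block 8632, 8516 and 10185 genes were called, and 7737, 7812 and 9690 of the 7774, 7856 and 9722 were shared with the same sign; besides the MHC class II and phagocytosis lists of IL4_IL13 against Control, it changed no other list call and lost no named gene. With library totals, added TNFa gave 2313 genes higher and 6089 lower. The stricter filter left 1024 genes at least 2-fold changed by IL4_IL13, from fewer genes tested. With an estimated correlation 1, 0 and 1 lists were called, and 1, 0 and 1 with the block as well, against 14, 11 and 15; fry, which tests movement without comparing a list to other genes, called 22 and 23 for IL4_IL13 and added TNFa. Leaving out 1 library gave 7179 to 9081, 7517 to 8727 and 9472 to 10371 genes, the highest of each without Control replicate 1, and 1574 to 2025, 2322 to 2389 and 3498 to 3789 changed at least 2-fold. Higher and lower genes were 3548 to 4741 and 3631 to 4340, 3807 to 4445 and 3710 to 4282, and 4667 to 5209 and 4805 to 5162. Genes moved back were 1753 to 2646 and moved further 2864 to 3824, lists called 14 to 15, 10 to 11 and 15. Depth limits genes with few counts in a group, such as Ccl17 in Control with 1 count. The cause of other changes was not tested.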

Other observations

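The family tests, and for neighbouring genes the tests of levels and without relatives, were chosen only after the result was seen. Gene families grouped by symbol stem were tested (200 families with at least 8 measured genes, camera, adjusted per comparison). Genes for the mitochondrial ribosome rose with IL4_IL13, with 37 of 48 Mrpl genes higher and 1 lower (median log2 fold change 0.30, adjusted p = 0.000248, and 0.716 with an estimated correlation). The rise was not particular to them. Of 72 Rpl genes 51 were higher and 0 lower (median 0.36, camera adjusted p = 1.2e-06, and 0.704 with an estimated correlation). Of 60 Rps genes 38 were higher and 2 lower (median 0.35, camera adjusted p = 0.000217, and 0.704 with an estimated correlation). Proteasome subunits rose too, with 8 of 8 Psma genes higher (median 0.37, adjusted p = 0.0173, and 0.704 with an estimated correlation). Guanylate-binding protein genes fell with IL4_IL13, 6 of 8 Gbp genes with a median of -1.91 (adjusted p = 0.0381, and 0.704 with an estimated correlation), and rose with added TNFa, with 5 higher and 1 lower and a median of 2.91 (adjusted p = 0.0313, and 0.792 with an estimated correlation). With library totals these directions held.

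With added TNFa, the families called lower included Haus, with 7 of 8 genes lower (median -1.05, adjusted p = 0.0214, and 0.792 with an estimated correlation), Cep, with 23 of 36 lower and 3 higher (median -0.43, adjusted p = 0.00361, and 0.792 with an estimated correlation), Kif, with 18 of 31 lower and 7 higher (median -1.32, adjusted p = 0.0214, and 0.732 with an estimated correlation), and Mcm, with 10 of 10 lower (median -1.28, adjusted p = 0.0287, and 0.794 with an estimated correlation). Also called lower were Arhgap (18 of 30 lower, 2 higher), Arhgef (11 of 15 lower, 3 higher) and Cbx (7 of 8 lower, 1 higher). So were Inpp (8 of 10 lower, 0 higher) and Osbpl (8 of 9 lower, 0 higher). Like those above, these calls use the preset correlation, and their adjusted p with an estimated correlation is not given here. Not called were Cdc (10 of 29 higher, 11 lower, adjusted p = 0.725), Cdk (7 of 26 higher, 10 lower, adjusted p = 0.734) and Anapc (1 of 10 higher, 5 lower, adjusted p = 0.468). Some Mcm genes are also in the cell cycle list. The Mrpl genes were 36 higher and 0 lower with TMM, but 11 higher and 5 lower with library totals.

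The hypothesis that neighbouring genes rise together with IL4_IL13 came from Mcf2l, F7 and F10, seen side by side on chromosome 8, and was tested on the same data. Neighbours were genes consecutive among the 11762 tested protein-coding genes, so genes that were not tested or not protein-coding could lie between them. Of 10101 neighbouring pairs with different symbol stems, 7 had both genes raised at least 8-fold, against 1.12 on average in 10000 shuffles (permutation p = 0.0002). The stem rule did not part relatives of the ribonuclease A family: without these and the Mcf2l and F7 pair 3 pairs remained (permutation p = 0.104), so the hypothesis was not upheld beyond these families and the pair that prompted it. Reads running on from one gene into the next may add to same-strand pairs, 5 of the 7 (permutation p = 0.0002), while the 2 pairs on opposite strands did not exceed chance (permutation p = 0.106). The 5 still count ribonuclease relatives and the Mcf2l and F7 pair set aside above. The difference between strands was not tested. In 1 same-strand pair, Rufy4 and Cxcr2, the downstream gene had 7.52 times the CPM of the upstream one, higher in 6 of 6 libraries, which argues against reads running on as the supply there. The other 4 stay open. Their gaps were 5.13 kb (Mcf2l, F7), 43.0 kb (Cdcp1, Tmem158), 56.1 kb (Ang2, Rnase2a) and 169 kb (Gm8113, Ear2).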
